A study of Caenorhabditis elegans with 4 samples.

How the data were processed

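Chromatin immunoprecipitation followed by sequencing was carried out on hermaphrodite Caenorhabditis elegans at L4, the last larval stage before adulthood, grown at 20 °C. The strain carries a transgene that encodes NHR-11 fused to green fluorescent protein and a FLAG tag. NHR-11 belongs to the nuclear hormone receptor family of transcription factors. Per the labels' protocols, worms were crosslinked with 2% formaldehyde, the chromatin was sheared by sonication, and DNA bound to the tagged protein was collected with an anti-GFP antibody. Part of each extract was kept as input, which stands for total genomic DNA. The labels describe 4 samples, 2 ChIP libraries and 2 input libraries, numbered as replicates 1 and 2. They do not say whether the replicates came from separate cultures.

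The authors deposited 3 lists of binding sites, 1 for each ChIP replicate and 1 for the whole series. Per the file headers, coordinates are in build WS220 of WormBase. Per the source column of the files, the sites were called with PeakSeq, a program that scores enrichment of ChIP reads over input. The version and settings of PeakSeq, the aligner and the way in which the replicates were combined for the series-level list are not given in the sources used here. Each site has a start, an end and 1 significance value. Neither the labels nor the file headers name this value. It was read as a p-value or q-value deposited by the authors, because all values lie above 0 and below 0.001 and nearly follow the numbering of the sites. Which of the 2 it is stays open. The files hold no read counts, signal heights or summits, so the sequencing depth behind a site is unknown and no interval based on reads is given. The site numbers in the lists run to 6839, 2616 and 2843 for the series-level list, replicate 1 and replicate 2, of which 40, 4 and 9 numbers are not among the listed sites. No list for the input libraries or for a strain without the tag was used here. Whether and how the input libraries entered the calling is not given, and no comparison of ChIP with input was made here.

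Significance values were turned into −log10 values, which serve to rank sites within a list. Values of different lists are the authors' own, and whether they share a scale is not known. The report sets them side by side. The closing section also takes ratios of them across lists, to test their scale and not a change in binding. Sites of 2 lists were called shared when they overlapped by at least 1 bp. Chance overlap was measured with 1000 circular shifts of the replicate 2 list, each with 1 random offset per chromosome (one-sided; the smallest p this can give is 0.000999). Agreement in strength was measured by Spearman's rho and Pearson's r of the −log10 values across sites that overlap one to one, with a 95% interval for rho from 2000 bootstrap samples. Sites are not replicates, and these values carry no p across samples. Shares of sites have exact Clopper-Pearson 95% intervals, which cover counting error only. Where a count was 0, the share it allows was set at 3 counts of the total. Shares per chromosome were tested against the chromosome's share of the covered span with exact two-sided binomial tests. The span of a chromosome was taken to run from its first base to the last base of the last site in any list, because no WS220 sequence was used here. Differences between classes of sites were tested with Fisher's exact test, two-sided. Families of tests were adjusted by the Benjamini-Hochberg method. Neighbouring sites depend on each other, so binomial and Fisher p-values count sites as units and are not p-values across replicates. The 2 replicate lists show the spread instead. The overlap function was tested on simulated data with 2600 sites, of which 60% were planted in a second list. It returned 60.8%, chance overlaps included.

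The number of sites per list, the overlap and rank agreement of the replicates, the share of series-level sites found in them, the share on X and the share in the central 33.3% of the autosomes were planned before the data were examined, with their alternatives, 24 gene lists, 13 motif words and the rule for named items. All other tests were added after the data had been seen. In the report these are the deciles of the replicate lists, the shares of the chromosomes other than X, the tests of sites found in neither replicate against those found in both, the single chromosomes' central segments, the test of autosomes against X, and the widths. In the closing section they are the windows, gaps and spacing, the gain in shared sites, the weaker and stronger 50% of the lists, the 1-Mb bins and the tests of a site on IV. Where the added tests are adjusted, the adjustment covers their own family. Of 14 planned results, 8 need gene positions or genome sequence in WS220 and were not run. These are the distance to 5′ ends, the annotation of sites, the genes with a site, the enrichment of the gene lists, the sites at small RNA genes, the motif words, the search for 6-mers and the signal at the nhr-11 locus. For X and the autosome centres, the planned second reference, the share of gene 5′ ends, was also not used. The gene table at hand is of assembly WBcel235, and coordinates were not converted between builds. The rule named the genes nearest to the 25 highest-ranked series-level sites, the nhr-11 and unc-119 loci, the leading members of each gene list and genes with several sites. Without gene positions it names the 25 sites themselves, by WS220 coordinates. The other regions named were chosen after their values were seen. Alternatives were a reciprocal overlap of at least 50%, midpoints within 100 bp, the upper 50% of each list by significance, merging of touching sites, each replicate's list alone, and the series-level sites that overlap both replicate lists. A further pair, leaving out chromosomes I and IV and rescaling their values, was chosen after seeing the data. Analyses were run in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.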

Results

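The series mapped where the transcription factor NHR-11, a nuclear hormone receptor, binds in the genome of L4 hermaphrodites. Binding sites were listed for ChIP replicate 1, for ChIP replicate 2 and for the series as a whole. Replicate 1 had 2612 sites and replicate 2 had 2834. The series-level list had 6799, which is 2.5 times the mean of the replicates. Sites had a median width of 397 bp in replicate 1, 401 bp in replicate 2 and 352 bp in the series-level list. They covered 1.35%, 1.45% and 3.07% of the span of the 6 chromosomes, respectively. The median −log10 significance was 5.09 in replicate 1, 5.11 in replicate 2 and 5.93 in the series-level list. The depth of the libraries is unknown. Sites are given by their WS220 coordinates. The genes, exons or introns at these positions were not analysed here, because no WS220 annotation was used.

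The strongest NHR-11 site of all 3 lists lay on chromosome II at 10541878 to 10554402. It was 12525 bp wide in the series-level list, 12480 bp in replicate 1 and 12241 bp in replicate 2, and its −log10 significance was 257, 115 and 114 in these lists. The site ranked second in the series-level list lay on chromosome I at 7078686 to 7086188, with a −log10 significance of 223. It ranked 4 in replicate 1 and 6 in replicate 2. A site on X at 16929321 to 16931980, 2660 bp wide, followed with 204 in the series-level list, and ranked 2 in both replicates. A site on V at 6220819 to 6230074 reached 179 and was 9256 bp wide. It was split into 3 sites in replicate 1 and 2 sites in replicate 2. Sites on IV at 14032616 to 14034689 and on I at 9379703 to 9382098 reached 156 and 153, and ranked 8 and 7 in each replicate.

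All 25 highest-ranked series-level sites were found in both replicate lists. The series holds no other ChIP libraries, so this is not an independent check. By the best-ranked overlapping site in each replicate, 15 of them were among the first 25 of both. For the site on V at 6220819, these ranks, 21 and 13, belong to different pieces that do not overlap. Of the 25 sites, chromosomes I and IV held 6 each, X held 5, II and V held 3 each, and III held 2. This tally rests on series-level values, which stood higher against the replicates' values on I and IV than elsewhere. The median ratio to the replicates' sum in shared sites was 1.39 there and 1.05 on the other chromosomes. Their widths ran from 515 to 12525 bp with a median of 2947 bp, and 20 of the 25 were at least 2 kb wide. The narrowest were on V at 13869462 to 13869976 (515 bp) and on III at 4237565 to 4238209 (645 bp). The III site ranked 3 in both replicates, with −log10 values of 76.0 and 78.2, and the V site ranked 6 and 5, with 63.6 and 70.2. Other sites of this group with a rank of 20 or better in both replicates were on X at 1503018 to 1505223, on X at 6740232 to 6744761, on X at 8035879 to 8036931, on II at 11633595 to 11637537, on V at 9342940 to 9344794 and on III at 4281691 to 4282743. At the other end, the site on I at 12549256 to 12553106 ranked 25 in the series-level list. It was covered by 3 separate sites in replicate 1, the best of them ranked 274, and by 4 in replicate 2, the best ranked 606. Across all series-level sites, wider sites had higher −log10 values (Spearman's rho 0.61 across sites).

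The first comparison asked how far the replicates gave the same sites. Of the replicate 1 sites, 2023 (77.5%, 95% interval 75.8 to 79.0) overlapped a replicate 2 site, and 2024 of the replicate 2 sites (71.4%, 69.7 to 73.1) overlapped a replicate 1 site. Random circular shifts of 1 list, used as a permutation test, gave a mean of 2.96% and a maximum of 5.51% for replicate 1, and 2.73% and 5.08% for replicate 2 (p = 0.000999, one-sided, the smallest that 1000 shifts can give). All 261 sites in the strongest decile of replicate 1 and all 283 in the strongest decile of replicate 2 were present in the other replicate. In the weakest decile the share was 41.6% (35.6 to 47.8) for replicate 1 and 33.5% (27.99 to 39.3) for replicate 2. Across the 1966 sites that overlapped one to one, Spearman's rho of the −log10 values was 0.79 (0.77 to 0.81) and Pearson's r was 0.94. The strongest site of replicate 1 without a partner was on V at 11078356 to 11079161, with a −log10 value of 7.72 and rank 760. In replicate 2 it was on II at 6835481 to 6837435, with 10.5 and rank 500. Both are in the series-level list. The labels do not say that the replicates came from separate cultures, so these values measure only the spread between 2 samples, which may be technical. A list from a strain without the tag was not used here, so the overlap does not separate sites of NHR-11 from regions enriched in any such ChIP.

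**Figure D1:**
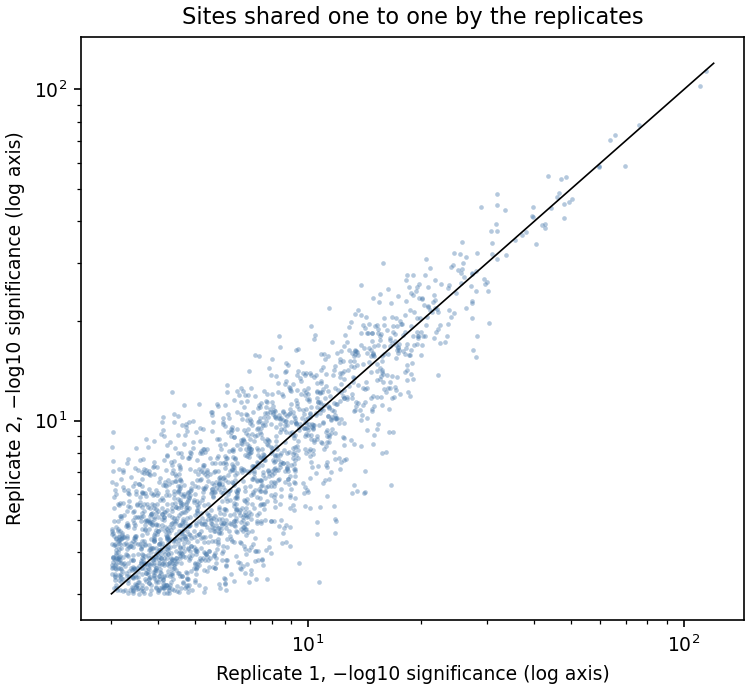
Significance of the 1966 sites that overlapped one to one between the replicates, as −log10 values on log axes, with replicate 1 on the horizontal and replicate 2 on the vertical axis. Each point is a site and the line marks equal values; points close in on the line at high values, and Spearman's rho is 0.79.

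The next comparison set the series-level list against the replicates. Nearly all replicate sites were in it, with 2597 of the 2612 replicate 1 sites (99.4%) and 2809 of the 2834 replicate 2 sites (99.1%). In the other direction, 1992 of its 6799 sites (29.3%, 28.2 to 30.4) were found in both replicate lists, 1329 (19.5%, 18.6 to 20.5) in 1 list and 3478 (51.2%, 50.0 to 52.3) in neither. Sites in both lists had a median width of 526 bp and a median −log10 value of 15.6. Sites in neither had medians of 262 bp and 4.12. In the strongest decile of the series-level list, with −log10 values of 20.2 and above, 677 of 679 sites were in both replicates. The share in both was 60.4% (56.7 to 64.1) in decile 3 and 1.32% (0.607 to 2.498) in decile 6. In each of deciles 7 to 10, with −log10 values of 5.01 or below, it was 0 of 680 (up to 0.441% by counting alone). Every site in a replicate list has a −log10 value of at least 3.00 there. In sites shared one to one, the series-level value had a median of 1.13 times the sum of the replicates' values. The cutoffs of the lists can therefore give this 0 by themselves, and it does not measure how well weak sites repeat. Agreement in the strong deciles is not an independent check either, because the series holds only these 2 ChIP libraries. Sites under 50 bp made up 4.24% of the series-level list, against 0.995% of replicate 1 and 0.882% of replicate 2.

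**Figure D2:**
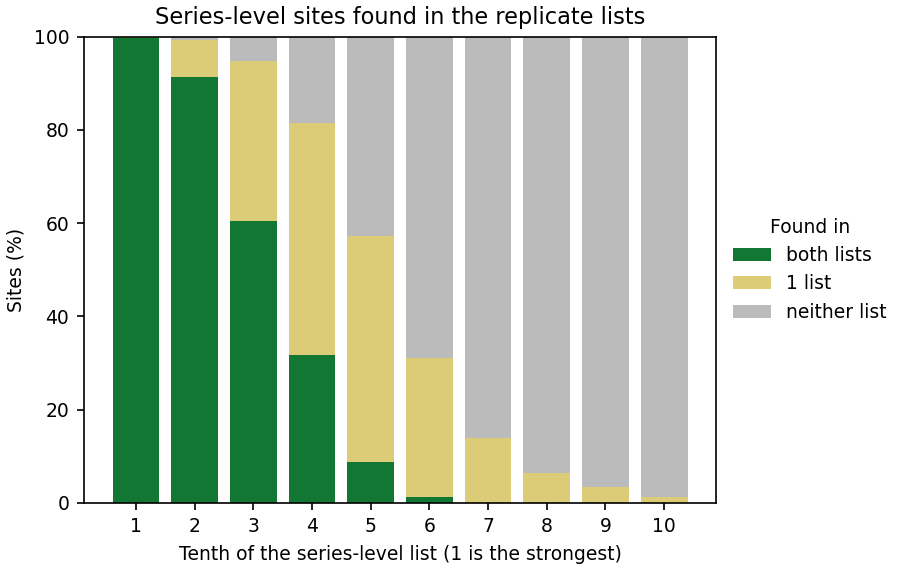
Share of series-level sites (vertical axis, percent) found in both replicate lists, in 1 list or in neither, for each decile of the series-level list from the strongest (1) to the weakest (10). The share in both lists is 99.7% in decile 1, 60.4% in decile 3 and 0 from decile 7 on.

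The strongest series-level site absent from both replicates was on IV at 9067439 to 9078963. It was 11525 bp wide, with a −log10 value of 70.8 and rank 48. The next one, on I at 14947100 to 14948949, had 14.9 and rank 1076. The IV site lay beside a pair of wide sites that all 3 lists hold. The nearer, at 9062418 to 9066037, had a −log10 value of 27.96 in replicate 1, 28.3 in replicate 2 and 55.3 in the series-level list. The other, at 9049854 to 9057093, had 11.5, 7.0 and 72.8. Whether these sites lie in nhr-11, which the transgene carries, was not analysed here.

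**Figure D3:**
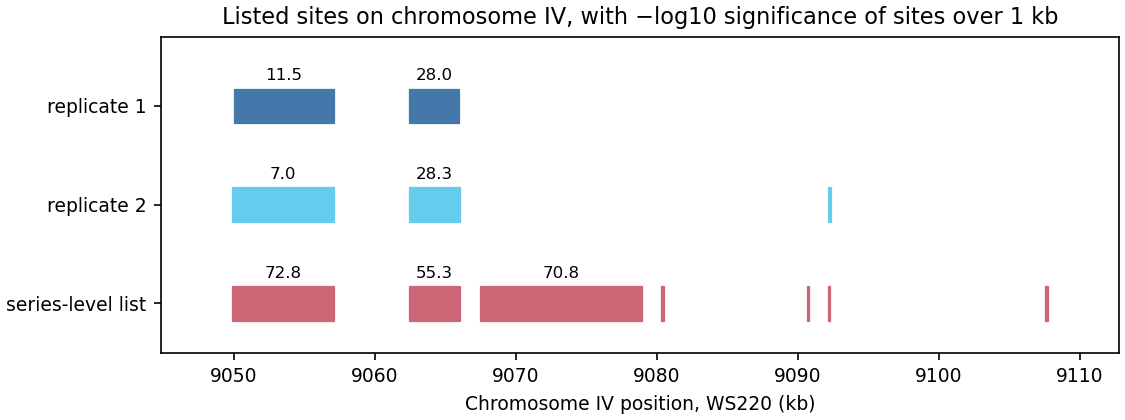
Sites listed within 30 kb of the strongest series-level site absent from both replicates, on chromosome IV (horizontal axis, WS220, in kb, drawn to scale) in each list, with the −log10 significance of sites wider than 1 kb printed above them. The widest site, with 70.8, stands in the series-level list alone.

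NHR-11 sites were not spread over the chromosomes in proportion to their span. Chromosome I was above its share of 14.98% of the span, with 19.4% of the replicate 1 sites (17.9 to 20.9), 17.5% of the replicate 2 sites (16.1 to 18.9) and 18.8% of the sites found in both (17.1 to 20.6). Chromosome IV, with 17.5% of the span, held 19.4%, 20.2% and 19.5% of these sites. Chromosome V was below its 20.9% of the span, with 14.5% of the replicate 1 sites (13.2 to 15.9), 15.6% of the replicate 2 sites (14.3 to 17.02) and 14.2% of the sites found in both. In density, V had 18.1 and 21.2 sites per Mb in replicates 1 and 2, and IV had 29.05 and 32.7. The differences on I, IV and V passed exact binomial tests in both replicates, with adjusted p between 4.88e-16 (V, replicate 1) and 0.0158 (IV, replicate 1) over 24 tests. Chromosomes II and III did not pass in either replicate, with adjusted p of 0.416 or more.

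Chromosome X held 17.04% of the replicate 1 sites (15.6 to 18.5), 16.7% of the replicate 2 sites (15.4 to 18.2) and 16.8% of the sites found in both (15.2 to 18.5), against 17.7% of the span (exact binomial p = 0.412, 0.192 and 0.304). In the series-level list the share on X was 15.2% (14.3 to 16.1), below the share of the span (exact binomial p = 4.45e-08). It was 14.03% in the upper 50% of that list by significance (exact binomial p = 1.23e-08). The low share did not hold in either replicate list. Without chromosomes I and IV, a setting chosen after seeing the data, X held 27.4% of the remaining series-level sites against 26.2% of the remaining span (exact binomial p = 0.0847).

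The series-level list had another chromosome distribution than the replicates. It held 3.09 times as many sites as the mean replicate on IV and 2.72 times on I, against 2.09 on III, 2.24 on II, 2.25 on X and 2.36 on V. Of the series-level sites found in neither replicate, 28.7% were on IV and 21.8% on I, compared with 19.5% and 18.8% of those found in both (Fisher's exact test, adjusted p = 1.67e-13 for IV and 0.00911 for I over 6 chromosomes). Chromosomes II, III and X had lower shares among the sites found in neither (Fisher's exact test, adjusted p = 0.0011, 1.55e-06 and 0.00264), and V did not pass (adjusted p = 0.285). Shares of the 6 chromosomes depend on each other, so higher shares on I and IV lower the others by construction. The 6 tests are therefore not separate results. No test was made among II, III, V and X alone. Together, I and IV held 38.8% of the replicate 1 sites, 37.7% of the replicate 2 sites and 44.6% of the series-level sites.

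**Figure D4:**
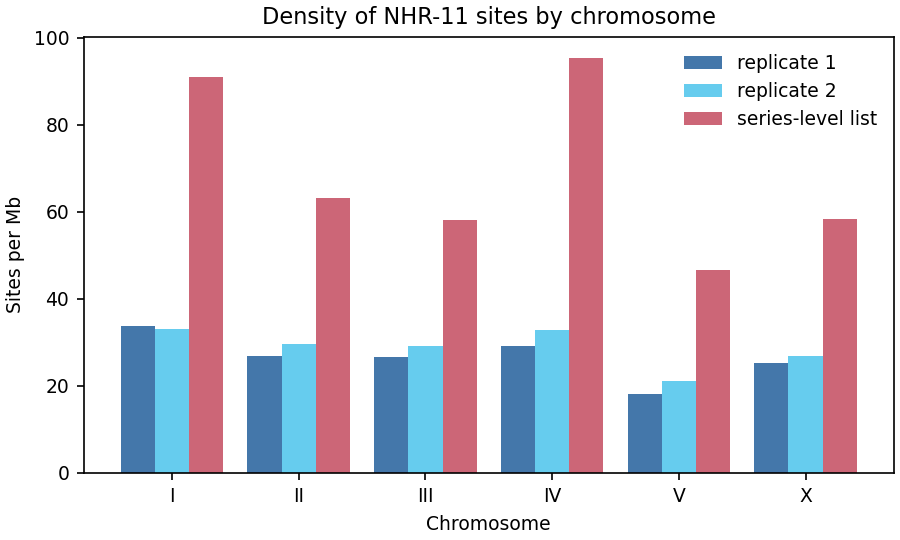
NHR-11 sites per Mb (vertical axis) on each chromosome in replicate 1, replicate 2 and the series-level list. Bars are single lists with no error bar; the series-level list reaches 90.9 sites per Mb on I and 95.4 on IV, and lies between 46.5 and 63.0 on the other chromosomes.

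Within the autosomes, NHR-11 sites lay more often in the middle of the chromosome. The central 33.3% of the length of the 5 autosomes held 44.99% of the replicate 1 sites (42.9 to 47.1), 45.8% of the replicate 2 sites (43.7 to 47.8), 45.4% of the sites found in both (43.0 to 47.8) and 43.7% of the series-level sites (42.4 to 45.02), more than the 33.3% that length alone gives. The exact binomial p was 2.42e-29, 7.69e-36, 2.21e-24 and 2.03e-60. Each autosome was above 33.3% in all these lists. In the sites found in both replicates, the share ran from 39.7% on IV (34.8 to 44.8) to 49.3% on V (43.3 to 55.3). On X the central segment held 33.9% of the replicate 1 sites (29.5 to 38.5) and 30.8% of the replicate 2 sites (26.7 to 35.2), and the tests against 33.3% did not pass (exact binomial p = 0.802 and 0.262). The difference between the autosomes and X passed Fisher's exact test in both replicates, with p = 1.6e-05 in replicate 1 and 1.31e-09 in replicate 2. The share of genes in the central segments was not analysed here.

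**Figure D5:**
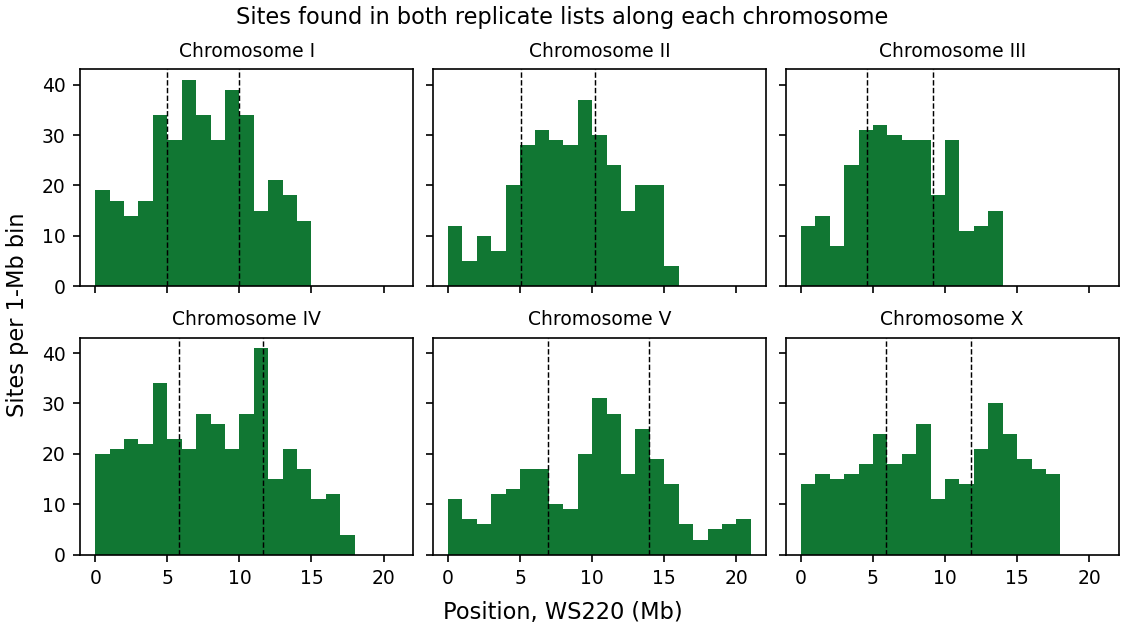
Number of sites found in both replicate lists per 1-Mb bin (vertical axis) along each chromosome (horizontal axis, Mb, WS220); dashed lines bound the central 33.3% of the length. On the autosomes 45.4% of these sites lie between the lines, and on X 31.7%.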

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

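The 3 alternatives run for the overlap of the replicates (reciprocal overlap, midpoints, upper 50%) kept it above chance (shares of 60.1% to 82.01%, each with a permutation p of 0.000999, the smallest possible) and the 6 run for the central 33.3% of the autosomes (each replicate alone, sites in both, upper 50%, without I and IV, rescaled) kept the share above that length (44.7% to 46.9%). The rank correlation of the −log10 values across shared sites was 0.77 in the upper 50% of each list. That setting narrows the range of values by construction, and whether this alone lowered the correlation was not tested. Under the other overlap rules the correlation stayed within its interval. The share of series-level sites found in both replicates was 25.8% with a reciprocal overlap of 50% of each site, 23.3% with midpoints within 100 bp, both stricter by construction, and 30.97% in the upper 50% of the lists. The upper 50% held 3400, 1306 and 1417 sites by construction, and merging changed no count because no sites touch. The low share on X in the series-level list (15.2%) was the result that depended on the list: with either replicate's list alone it was 16.7% to 17.04%, and in the sites found in both it was 16.8%, no longer past the threshold against the share of the span. It was 14.03% in the upper 50% of the series-level list, where it stayed past the threshold (exact binomial p = 1.23e-08). Leaving out I and IV turned it to 27.4% against 26.2% of the remaining span (exact binomial p = 0.0847), and rescaling I and IV gave 16.8% (exact binomial p = 0.0818). Both of these settings were chosen after seeing the data. Rescaling takes sites from I and IV alone, so a rise of the share on X is built in. The rescaled list held 6137 sites. No paired analysis was possible because no list of the input libraries was used here, so ChIP and input could not be fitted with the replicate number as a block. The alternatives for the 8 planned results that need WS220 genes or sequence were not run. Read depth is unknown, which leaves open whether sites found in 1 list are absent or too shallow in the other.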

Other observations

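The tests of the weaker and stronger 50% of the lists, of the 1-Mb bins and of the chromosome IV site were chosen after the results were seen, as were the rescaling of chromosomes I and IV and the descriptions of widths, windows and gaps. The tests of the gain in shared sites and of spacing were set before their results were seen. The test of the weaker and stronger 50% was changed after its result was seen. It had first set the replicate lists against the same difference in the series-level list, which came out with the opposite sign (-5.75 percentage points) and so gave no usable bound. It was then set against the excess of sites found in neither replicate over sites found in both. The test of missing site numbers was also changed after its result was seen. It had first covered the first 10% of the numbers, where 0 are missing, a range that does not reach the ranks of the neighbouring site (398 and 943).

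Very wide sites formed a small class. In the series-level list 17 sites were 4 kb or wider, and 16 of them were in both replicates. Beyond those named above they include sites on II at 8741853 to 8748223 (6371 bp, rank 7), on II at 5333727 to 5339858 (6132 bp, rank 51), on X at 4141927 to 4146940 (5014 bp, rank 12) and on V at 723825 to 728347 (4523 bp, rank 71). Being in both replicates needed an overlap of only 1 bp, and it is not an independent check of the series-level list. In the same order, the best-ranked overlapping sites in replicates 1 and 2 were 3559 and 2386 bp, 1077 and 2927 bp, 1579 and 1714 bp, and 4451 and 2246 bp wide. Where a series-level site was split, these are widths of single pieces. The II site at 8741853 was covered by 2 sites in replicate 1 and 3 in replicate 2, and the X site by 2 in each. On X the best-ranked pieces were different ones, at 4144305 to 4145883 in replicate 1 and 4141972 to 4143685 in replicate 2. At such sites the widths do not show whether the full width repeated. At the strongest site, on II at 10541878, the best-ranked sites were 12480 and 12241 bp wide. Among 1002 windows of 100 kb, 237 (23.7%) held no site found in both replicates, where a Poisson distribution with the same mean of 1.99 gives 13.7%. The fullest window, on II from 6800001 to 6900000, held 10 such sites, in a 1-Mb bin that held 31. The longest stretches without any series-level site were 265 kb on X, from 59390 to 324014, and 223 kb on V, from 2809772 to 3032496. Neither replicate had a site in these stretches.

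Sites found in both replicates lay somewhat closer together than random placement gave. Their midpoints had a median distance of 26.9 kb, below all of 1000 random placements that kept the number of sites in each 1-Mb bin (mean 31.5 kb, range 29.6 to 34.2 kb). This argues against random placement within bins. Gene spacing is a candidate explanation that was not tested, because no WS220 annotation was used.

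The surplus of series-level sites on chromosomes I and IV is the pattern most worth following up. A few regions with many extra sites are argued against, since 93.9% of the 33 bins of 1 Mb on I and IV had a higher ratio of series-level to replicate sites than the median bin elsewhere. More weak sites on I and IV in every list are argued against, at the strengths that the replicate lists reach, since the weaker minus the stronger 50% gave -2.91 percentage points in replicate 1 and -2.47 in replicate 2 (95% interval up to 0.842 and 1.06), against an excess of 12.2 points (9.54 to 14.9) in the sites found in neither. As a hypothesis, significance may have been scaled differently on I and IV in the series-level list: sites that all 3 lists share one to one had a series-level −log10 value of 1.39 times the sum of the replicates' values there (734 sites) and 1.05 times elsewhere (1186 sites), a difference of medians of 0.345 (0.329 to 0.363), and dividing the values on I and IV by the ratio of these medians, 1.33, left 38.6% of 6137 sites there, against 38.8% and 37.7% in the replicates. The divisor was taken from these same lists, and dividing I and IV alone can only lower their share. The fall toward the replicates' share is therefore partly built in and is not separate support. The step that would scale significance by chromosome stays open, sites too weak for the replicate lists were not covered, and no biological explanation was tested.

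The wide site on IV at 9067439 to 9078963, with a −log10 value of 70.8 in the series-level list and absent from both replicates, is a separate case. Its farther neighbour, at 9049854 to 9057093, had 11.5 and 7.0 in the replicates and 72.8 in the series-level list, whereas the nearer, at 9062418 to 9066037, had 27.96, 28.3 and 55.3. A site as strong as the farther neighbour that was numbered and is missing from the replicate lists as held here is argued against: the numbering follows rank to within 17 places, and the lowest missing numbers, 1518 and 2210, allow −log10 values of up to 4.58 and 3.71. This test sees only sites left out after numbers were given, so a site dropped before that stays open. A weaker missing site stays open. The gain that other IV sites show is argued against, for a site that fell under the replicate cutoffs. Both replicate lists reach down to −log10 values of 3.00. In 374 IV sites shared one to one, the series-level value had a median of 1.39 times the replicates' sum (quartiles 1.29 and 1.53). At these ratios, values under the cutoffs, or up to 4.58 and 3.71, fall far short of 70.8. The farther neighbour reached 72.8 from replicate values of 11.5 and 7.0, which are well above those allowed here. The same gain at the allowed values would also fall short of 70.8. A gain larger than that stays open. The highest value of the other IV sites absent from both replicates, 14.4, decides nothing about a site chosen for its height. Extra copies of transgene DNA remain open and untested, because the genes in this interval were not analysed here.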
